A study of Mus musculus with 48 samples.

How the data were processed

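The series holds 48 Agilent 2-colour arrays of the mouse whole-genome design, 1 file per array. Per the labels, the sample was labelled with Cy5 and the pool of unsorted cells with Cy3, and no dye-swapped array was used here, so a dye effect that is the same on every array cancels between groups and was not estimated. Per the file headers, the deposited red and green intensity values were measured from the scanned images by Feature Extraction, versions 10.7.3.1 and 10.5.1.1, with a foreground and a local background for each spot. Per the file headers, the deposited log10 ratio of each spot had been background-corrected and dye-normalised by Feature Extraction, and the authors' series values held the same ratios. The log2 ratios used here were computed from the deposited intensities and not taken from the authors. No reads were aligned, and a genome build was not given in the sources used here. Some pairs of a non-irradiated Negative array with a Sublow or Low array, or with an irradiated Low or High array, correlated below -0.3 (lowest -0.395), and the direction stated by the labels was kept.

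Median foreground intensities were corrected with normexp (offset 50), ratios were normalised by loess within each array with control spots at weight 0, spots flagged as outliers (0.684%) were set to missing, and spots of a probe were averaged. Of 39429 probes, 34132 were well above background in the Cy5 channel on at least 3 arrays of a group. Each of 27491 genes was represented by its brightest probe. Symbols came from the accession (26055 probes), a symbol or synonym (4125) or another accession (16) in the reference table, and 9233 probes kept the name in the file. The array of the pool against itself was left out of the fit, and the other 47 arrays formed 9 groups.

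One limma model was fitted with the 9 groups and the array set, the empirical Bayes variance was shared over all groups, and p-values were adjusted by Benjamini and Hochberg within a comparison, with calls at an adjusted p under 0.05. The set term rests on non-irradiated mice, which were in both sets, and takes the set difference to be the same in every group. Whether irradiation acted differently in the gates was tested by interaction contrasts, by a moderated F over the 4 gates and by a moderated t for High minus Low. Where a probe was not well above background on any array of a group, no fold is given. The probes of Itgam in Sublow, Csf1r in irradiated Negative and Low and Msi1 in gates against unsorted cells gave opposite directions, and these genes are not named for those comparisons. For Bmi1, Hopx, Muc2, Cdkn1a, Dclk1, Npm1, Nkd1, Pappa2, Atf7 and Zfp488, another probe was near 0 or of the opposite sign in at least 1 comparison given, so those values rest on the brightest probe. Probes of some other genes differed in the size of the change, as for Slc7a15 in Negative (5.03 and 2.49), and the standard errors do not include this.

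The genes named in the text followed a rule fixed before the data were examined, as were the tests, the gene lists and the alternatives except where stated. In each comparison they were the 6 largest increases and the 6 largest decreases with the same sign in every array of the smaller group, or in both array sets for gates, leaving out unnamed, RIKEN, LOC and predicted genes. Up to 4 of the largest called members of each list followed, of which the text gives a part, chosen by rank among those whose call was kept when any 1 mouse was left out. Sox9, Lgr5, Olfm4, Ascl2, Bmi1, Hopx, Lrig1, Dclk1, Chga, Lyz1, Muc2, Alpi, Mki67 and Cdkn1a were given whatever they showed. Some genes that met the rule are not reported.

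The 28 gene lists held 505 members, of which 492 were tested. They were CBC stem cell, reserve stem cell, enterocyte, goblet cell, Paneth cell, enteroendocrine cell, tuft cell, S phase, G2/M phase, p53 target, homologous recombination and DNA repair, Wnt target, Notch pathway, ribosome biogenesis, interferon response, MHC class II presentation, regenerative and fetal-like epithelium, antimicrobial and mucosal defence, insulin and IGF axis, fatty acid oxidation and PPAR target, cholesterol biosynthesis, immediate-early and dissociation, T cell and intraepithelial lymphocyte, B and plasma cell, myeloid cell, stromal and smooth muscle, endothelial cell, and erythroid cell. Each was tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. Under the alternatives the lists were tested on the moderated statistics with the preset correlation, which gives slightly different p-values.

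The labels give a replicate number within each treatment, which is read here as the mouse; they do not say that a number names the same mouse in every gate. Arrays of 2 gates with the same number deviated together from their group means (median r 0.287, 52 of 60 pairs above 0.1), those with different numbers did not (median -0.118), and non-irradiated and irradiated arrays of 1 slide did so as well (median r 0.333, 11 of 12 above 0.1). The consensus correlation was 0.0902 within mice and 0.202 within slides. Every slide of sorted cells held a single gate, and the arrays of mice 4 to 7 of a gate shared 1 slide. Differences between gates were therefore also differences between slides. With slide as a random block, 17082 genes were called for Negative, 11637 for Sublow, 11006 for Low and 12419 for High. Fits with mouse or slide as a block were alternatives written before the data were examined.

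The pipeline was tested on simulated data made from 25798 genes with no missing value. In the Low gate, irradiation effects of 1.5-fold, 2-fold and 4-fold were called for 44.8%, 83.6% and 97% of the changed genes, and differences of irradiation effects between High and Low for 26.9%, 46.3% and 93.9%. Only 67, 67 and 66 genes were changed by these folds, and noise was drawn independently for each array, without slide or mouse correlation. The recovered shares need not hold for the real data, where far more genes were called. Arrays were also regrouped at random with the numbers of each group kept, and the closing section gives these counts.

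The alternatives were no background correction, the processed ratios of Feature Extraction, the authors' series values, Aquantile scaling between arrays, no filter, a stricter filter, the mean of all passing probes, slide or mouse as a random block, mouse as a fixed block among non-irradiated gates, slide as a fixed block among mice 1 to 3, no array set term, mice 1 to 3 alone, mice 4 to 7 alone and each mouse left out in turn. After seeing the data, 3 were added: the scan session as a covariate, the fit without the non-irradiated Low array of mouse 3 and the fit without the irradiated High array of mouse 3. R 4.3.3, limma 3.58.1 and data.table (version 1.17.8) were used.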

Results

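The jejunal epithelium of Sox9-EGFP mice, which carry a fluorescent reporter under regulatory sequence of the crypt transcription factor Sox9, had been sorted by reporter level into 4 gates, Negative, Sublow, Low and High. RNA of each gate was hybridised to 2-colour whole-genome arrays against a pool of unsorted epithelial cells from non-irradiated mice. Each gate was measured in 7 non-irradiated mice and in 3 mice taken 5 days after 14 Gy to the abdomen, with gates set, per the labels, on the reporter profile of non-irradiated mice sorted in the same run. Unsorted cells were measured in 7 non-irradiated mice, which gave 47 arrays in 9 groups. On these arrays 56.0% to 86.4% of probes were well above background in the sample channel, 27491 genes entered the tests, and the number of arrays per group, 7 or 3, limits the precision. In Negative this share was 65.6% to 86.4% on non-irradiated and 56.2% to 61.4% on irradiated arrays, a difference that the model did not adjust for. All irradiated arrays belonged to 1 array set with non-irradiated mice 1 to 3, so the set was a term of the model. No slide held sorted cells of more than 1 gate, so differences between gates were also differences between slides. Fold changes are on the log2 scale, values after ± are standard errors of limma's fit unless named otherwise, and genes with an adjusted p under 0.05 are called. The comparisons of gates ask which cells each reporter level holds, and those of treatments ask how each gate's cells differ during regeneration of the crypts.

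Sox9 itself followed the gates. Its log2 ratio to the pool was -0.24 ± 0.55 (SD, n = 7) in Negative, 1.17 ± 0.26 in Sublow, 2.17 ± 0.25 in Low and 3.24 ± 0.40 in High of non-irradiated mice, against 0.11 ± 0.26 in unsorted cells. In irradiated mice it was 0.21 ± 0.53 (SD, n = 3), 0.89 ± 0.30, 1.68 ± 0.15 and 2.82 ± 0.51 in the same order of gates. The sort was on a reporter of Sox9, so these values describe the gates and are not independent of them.

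**Figure D1:**
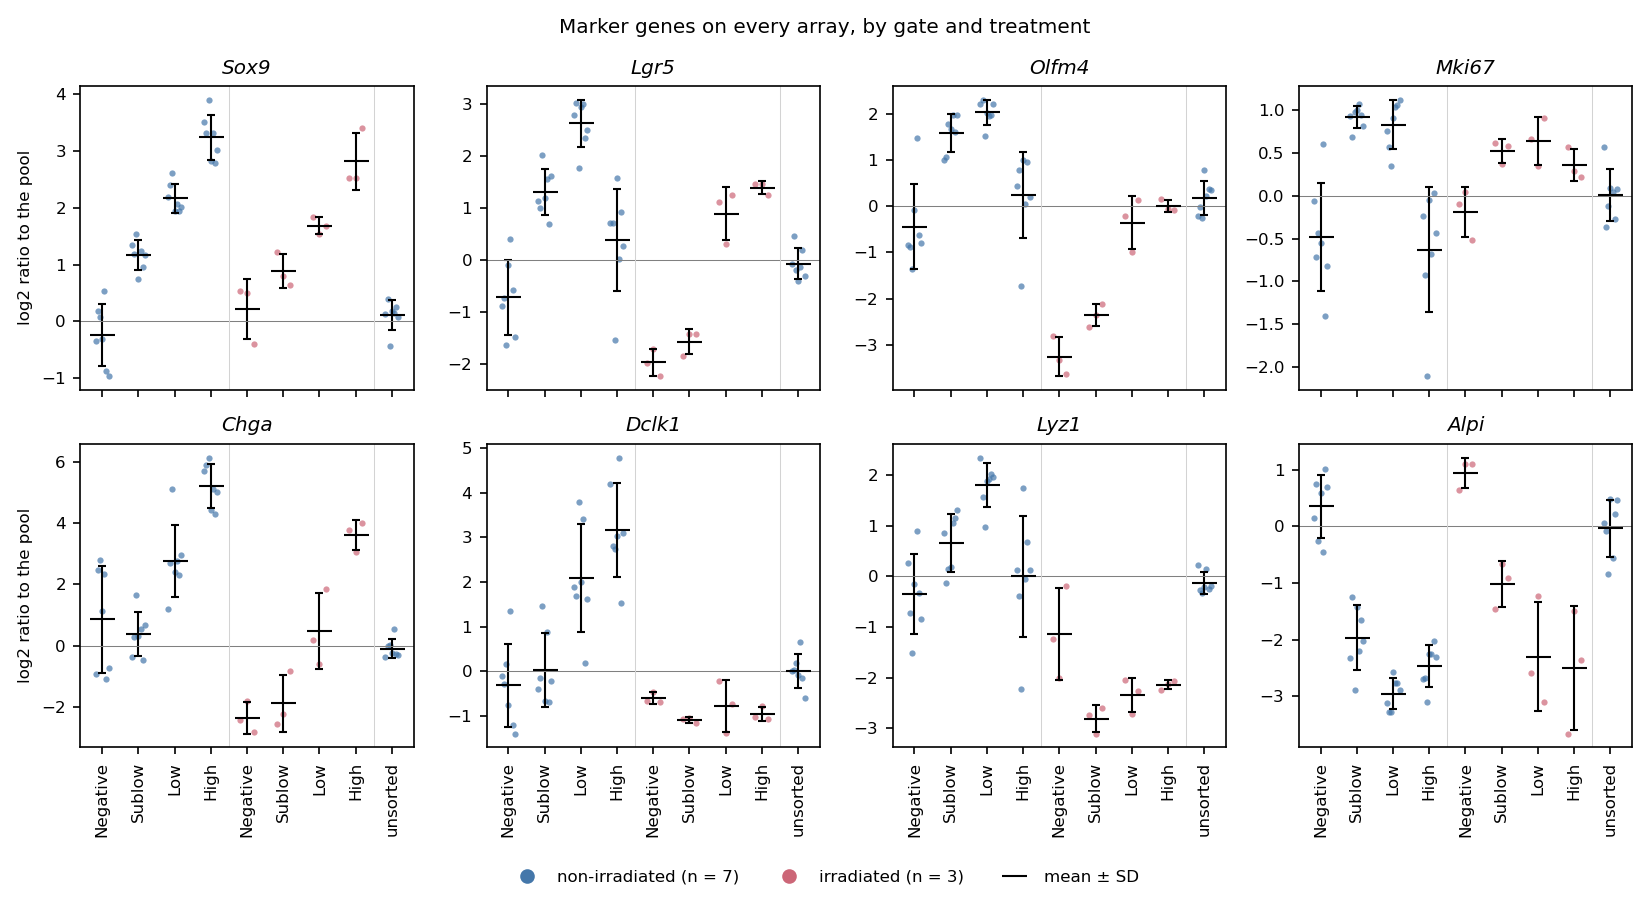
Each panel plots the log2 ratio of 1 marker gene to the pool of unsorted cells (y axis) for every array by gate (x axis), non-irradiated in blue and irradiated in red, with the group mean ± SD and no adjustment for the array set. Sox9 rises from -0.24 in Negative to 3.24 in High of non-irradiated mice, and Lgr5 has its highest non-irradiated mean in Low, at 2.63.

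In non-irradiated mice the 14 marker genes fixed in advance divided the gates by cell type. Against the mean of the other 3 gates, Sox9 was lower in Negative (-2.43 ± 0.14) and Sublow (-0.55 ± 0.14) and higher in Low (0.78 ± 0.14) and High (2.21 ± 0.14). Lgr5, Olfm4 and Ascl2, genes of crypt base columnar (CBC) stem cells, were higher in Low (2.30 ± 0.24, 1.56 ± 0.23 and 1.66 ± 0.19) and lower in Negative (-2.16 ± 0.24, -1.72 ± 0.23 and -1.71 ± 0.19) and in High (-0.69 ± 0.24, -0.81 ± 0.23 and -0.55 ± 0.19). In Sublow, Olfm4 (0.97 ± 0.23) and Ascl2 (0.59 ± 0.19) were higher, and Lgr5 (0.55 ± 0.24) missed the threshold with an adjusted p of 0.0526. Bmi1 and Hopx, associated with reserve stem cells, were lower in Negative (-0.79 ± 0.09 and -1.08 ± 0.14) and Sublow (-0.25 ± 0.09 and -0.75 ± 0.14), higher in High (0.93 ± 0.09 and 1.69 ± 0.14) and not called in Low (0.11 ± 0.09 and 0.15 ± 0.14). Lrig1, an inhibitor of epidermal growth factor receptors, was -1.31 ± 0.13 in Negative, 0.49 ± 0.13 in Sublow, 1.1 ± 0.13 in Low and, not called, -0.28 ± 0.13 in High. The enteroendocrine marker Chga and the tuft cell marker Dclk1 were higher in High (3.89 ± 0.41 and 2.58 ± 0.34) and lower in Negative (-1.94 ± 0.41 and -2.08 ± 0.34) and Sublow (-2.58 ± 0.41 and -1.61 ± 0.34). Each value is a difference from the mean of the other gates, so a large excess in 1 gate makes the others lower. The mean log2 ratio of Chga to the pool was 0.85 in Negative and 0.38 in Sublow, above the -0.10 of unsorted cells. That of Dclk1 was -0.32 and 0.03, against 0.004 in unsorted cells. In Low, Dclk1 was higher (1.12 ± 0.34) and Chga was not called (0.62 ± 0.41). Lyz1, the lysozyme of Paneth cells, was higher in Low (1.70 ± 0.26), lower in Negative (-1.16 ± 0.26) and High (-0.70 ± 0.26) and not called in Sublow (0.16 ± 0.26). Muc2, the goblet cell mucin, and Alpi, the brush border alkaline phosphatase, were higher in Negative (2.44 ± 0.18 and 2.82 ± 0.21), lower in Low (-1.42 ± 0.18 and -1.59 ± 0.21) and High (-1.33 ± 0.18 and -0.95 ± 0.21) and not called in Sublow (0.32 ± 0.18 and -0.27 ± 0.21). Mki67, a proliferation antigen, was higher in Sublow (1.01 ± 0.18) and Low (0.89 ± 0.18) and lower in Negative (-0.85 ± 0.18) and High (-1.05 ± 0.18). Cdkn1a, the cell cycle inhibitor p21, was higher in High (1.75 ± 0.18), lower in Sublow (-1.27 ± 0.18) and Low (-0.84 ± 0.18) and not called in Negative (0.36 ± 0.18). In High, leaving out non-irradiated mouse 3 or 5 ended the calls of Lgr5 (adjusted p 0.0589 and 0.0833), Ascl2 (0.0735 and 0.0986) and Lyz1 (0.0909 and 0.088). Lrig1 was called without mouse 2, 4 or 6 (0.0421, 0.042 and 0.0208) or with mouse as a random block (0.0483). In Sublow, Ascl2 was lost without mouse 3 (0.0816) and Bmi1 without mouse 4 (0.0871) or with slide as a random block (0.0948). Muc2 was called without mouse 3 (0.0383) and Lgr5 without mouse 2, 4 or 6 (0.0397, 0.0242 and 0.034) or with the mouse block (0.0419). In Negative, Cdkn1a was called without mouse 5 (0.0393) or without the Low array of mouse 3 (0.0232).

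The Negative gate had the transcripts of differentiated absorptive and goblet cells. Against the other 3 gates, 18657 of 27490 genes were called, 10130 higher and 8527 lower. The largest increases were in Cyp3a25 (5.04 ± 0.28), a drug-metabolising cytochrome, Slc7a15 (5.03 ± 0.31), an amino acid transporter, Gdpd2 (4.95 ± 0.26), a phosphodiesterase, the glucose transporter Slc2a2 (4.43 ± 0.31) and the kinase Sgk2 (4.40 ± 0.24). The largest decreases were in the peptide hormone genes Nts (-3.40 ± 0.54), Tac1 (-2.93 ± 0.41) and Iapp (-2.84 ± 0.22), in Lrp11 (-3.10 ± 0.33), in Kctd12 (-3.04 ± 0.39) and in the cannabinoid receptor Cnr1 (-2.85 ± 0.41). All 26 enterocyte genes were higher (median 3.14, camera adjusted p 1.28e-14), among them the cobalamin receptor Cubn (4.39 ± 0.31) and the fatty acid binding protein Fabp2 (4.31 ± 0.28). Of 16 goblet genes, 11 were higher and 5 not called (0.00145), with Clca1 at 3.45 ± 0.33 and Zg16 at 2.89 ± 0.23. Of 24 interferon response genes, 18 were higher and 6 not called (1.24e-05), with the antiviral Mx1 at 3.01 ± 0.18 and Isg15 at 2.36 ± 0.18. Markers of T cells and intraepithelial lymphocytes, which are not epithelial, moved with these groups, 17 of 19 higher and 2 not called (8.64e-06), with granzyme Gzma at 2.34 ± 0.26 and Cd8a at 2.12 ± 0.22. Among 18 CBC genes 16 were lower and 2 higher (3.22e-05). Among 25 S phase genes 22 were lower, 2 higher and 1 not called (9.53e-06). Among 32 enteroendocrine genes 30 were lower, 1 higher and 1 not called (1.13e-07), against a mean that includes High, where most were higher. Smoc2 (-1.76 ± 0.14) and Mcm2 (-1.39 ± 0.14), a subunit of the replicative helicase, were among them. With p-values adjusted over the list alone, 31 enteroendocrine genes were lower and the other counts were the same. None of these list calls held with an estimated correlation, where the adjusted p = 0.328 for enterocyte, 0.401 for goblet and 0.397 for each of the other lists.

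The Sublow gate had the transcripts of dividing cells. Of 27490 genes, 13745 were called, 4872 higher (35.4%) and 8873 lower, and the processed ratios of Feature Extraction gave 47.3% higher. Of 25 G2/M genes 24 were higher and 1 lower (median 1.01, camera adjusted p 3.26e-15). Of 25 S phase genes 23 were higher, 1 lower and 1 not called (6.82e-14). Of 20 homologous recombination and DNA repair genes 18 were higher and 2 not called (4.52e-12), and all 22 ribosome biogenesis genes were higher (2.28e-13). Among them were the spindle checkpoint kinase Bub1 (1.38 ± 0.17), cyclin A2 gene Ccna2 (1.32 ± 0.17) and the ribonucleotide reductase subunit Rrm2 (1.29 ± 0.16). The mitotic kinase Pbk (1.41 ± 0.19), the goblet gene Clca1 (1.54 ± 0.33), Gsdmc3 (1.50 ± 0.27), a gasdermin, Proca1 (1.41 ± 0.48) and Lrr1 (1.35 ± 0.15) were the other largest increases. Of 16 goblet genes 10 were higher and 6 not called (0.000103). Of 18 CBC genes 11 were higher, 2 lower and 5 not called (0.00142). Enteroendocrine genes were lower in 30 of 32 members and higher in 2 (1.17e-09), tuft genes were lower in 16 of 18 with 2 not called (1.18e-06), and enterocyte genes were lower in 21 of 26 with 5 not called (2.35e-06). The mean of the other gates includes High, where most enteroendocrine and tuft genes were higher, and Negative, where all enterocyte genes were. The largest decreases were in the alpha-fetoprotein gene Afp (-5.89 ± 0.71), Nts (-3.69 ± 0.54), the sialic acid receptor Siglecf (-3.44 ± 0.45), the cytochrome Cyp4b1 (-3.40 ± 0.27), the protease Pappa2 (-3.38 ± 0.40) and the intermediate filament Vim (-3.17 ± 0.31). Lymphocyte markers were lower in 15 of 19 members with 4 not called (0.000643), with Gzma at -1.41 ± 0.26, and immediate-early and dissociation genes in 13 of 19 with 6 not called (0.00456). When adjusted over the list alone, 12 CBC genes and 19 repair genes were higher and the other counts were the same. No list call held with an estimated correlation, where the adjusted p = 0.24 for G2/M, 0.239 for S phase, repair and ribosome biogenesis, 0.461 for the lymphocyte and immediate-early lists and 0.432 for the others.

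The Low gate had the transcripts of CBC stem cells and Paneth cells together with those of dividing cells. Of 27490 genes, 13187 were called, 5163 higher (39.2%) and 8024 lower, and the processed ratios of Feature Extraction gave 47.3% higher. Among 18 CBC genes 16 were higher and 2 lower (median 1.35, camera adjusted p 2.96e-11), with Lgr5 at 2.30 ± 0.24, Tnfrsf19 at 2.05 ± 0.21 and Ascl2 at 1.66 ± 0.19. Of 6 reserve stem cell genes 3 were higher and 3 not called (0.00594), with the RNA-binding Mex3a at 1.67 ± 0.12. Of 20 Wnt target genes 16 were higher, 2 lower and 2 not called (1.1e-10), with the feedback inhibitor Nkd1 at 1.64 ± 0.17, and this call held with an estimated correlation (adjusted p = 0.0458). The Wnt target list includes Sox9, whose reporter defined the gates, and shares members such as Lgr5, Ascl2 and Tnfrsf19 with the CBC list. All 14 Paneth genes were higher (median 1.61, 1.04e-09), and outside the list the cryptdins Defa25 (2.29 ± 0.28), Defa17 (2.21 ± 0.27) and Defa31 (2.17 ± 0.27) were among the largest increases. Cryptdins are antimicrobial peptides with near-identical sequences, and the specificity of their probes, and of those of Zbtb46 and Atf7 below, was not tested. The transcription factor Zbtb46 (2.25 ± 0.46) and the protocadherin Pcdh8 (2.11 ± 0.20) were also among the largest increases. Of 25 G2/M genes 24 were higher and 1 lower (5.48e-11). Among 25 S phase genes 22 were higher, 1 lower and 2 not called (1.64e-12), with the helicase subunit Mcm7 at 1.21 ± 0.13. Of 32 enteroendocrine genes 15 were higher, 1 lower and 16 not called (8.95e-05), with Neurog3, the factor that specifies this lineage, at 1.56 ± 0.19 and the somatostatin gene Sst at 1.52 ± 0.21. All 26 enterocyte genes were lower (median -1.60, 6.05e-15). Of 24 interferon response genes 18 were lower and 6 not called (7.62e-07), with Mx1 at -1.91 ± 0.18. Of 19 lymphocyte markers 17 were lower and 2 not called (9.87e-06), with Gzma at -1.48 ± 0.26. The largest decreases were in Spink1 (-2.88 ± 0.26), a trypsin inhibitor, the cytochromes Cyp3a11 (-2.82 ± 0.36), Cyp3a16 (-2.59 ± 0.31) and Cyp3a25 (-2.47 ± 0.28), the fatty acid binding protein Fabp1 (-2.67 ± 0.29) and Slc7a15 (-2.54 ± 0.31). Adjusted over the list alone, 17 Wnt targets were higher, 18 lymphocyte markers lower and the other counts the same. With an estimated correlation the adjusted p = 0.053 for CBC and reserve stem cells, 0.139 for Paneth, 0.204 for G2/M and interferon response, 0.116 for S phase, 0.506 for enteroendocrine, 0.103 for enterocyte and 0.322 for the lymphocyte list.

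The High gate had the transcripts of enteroendocrine and tuft cells. Of 27490 genes, 14111 were called, 7610 higher and 6501 lower, and with the processed ratios of Feature Extraction the share called higher went from 53.9% to 44.5% and the median of all genes from -0.02 to -0.11. The largest increases were in Afp (7.62 ± 0.71), in Nts (5.41 ± 0.54) and Tac1 (4.79 ± 0.41), which encode neurotensin and substance P, and in the secretory granule genes Chgb (4.96 ± 0.50), Cpe (4.79 ± 0.44) and Scg2 (4.64 ± 0.46). Among 32 enteroendocrine genes 29 were higher, 2 lower and 1 not called (median 3.40, camera adjusted p 7.58e-14). Of 18 tuft genes 16 were higher, 1 lower and 1 not called (median 2.41, 1.06e-08), with the signalling regulator Rgs13 at 3.92 ± 0.44 and the prostaglandin synthase Ptgs1 at 3.29 ± 0.35. Of 19 immediate-early and dissociation genes, which also respond to cell isolation, 14 were higher and 5 not called (0.000642), with Nr4a1 at 2.06 ± 0.28. All 25 G2/M genes were lower (median -1.06, 1.45e-11), with Ccna2 at -1.42 ± 0.17. Of 25 S phase genes 23 were lower and 2 not called (1.72e-09), with Rrm2 at -1.44 ± 0.16. Of 16 goblet genes 11 were lower and 5 not called (7.23e-06). Of 14 Paneth genes 12 were lower and 2 not called (0.000541). The largest decreases were in Clca1 (-2.72 ± 0.33), the pentraxin Mptx1 (-2.50 ± 0.26), the goblet-enriched Rep15 (-2.16 ± 0.22), the secretory lineage factor Atoh1 (-2.10 ± 0.19), the potassium channel Kcnk6 (-2.09 ± 0.22) and Tcim (-2.08 ± 0.24). With p-values adjusted over the list alone, 24 S phase and 13 Paneth genes were lower and the other counts were the same. No list call held with an estimated correlation, where the adjusted p = 0.3 for enteroendocrine, tuft, G2/M, S phase and goblet, 0.368 for the immediate-early list and 0.385 for Paneth.

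High and Low, the gates with the highest non-irradiated mean of Dclk1 and of Lgr5 in that order, were also compared directly. Of 27491 genes 13463 were called, 8500 higher in High (63.1%) and 4963 lower, against 52.8% higher with the processed ratios of Feature Extraction. The largest increases in High were in Afp (6.34 ± 0.87), the surface protein Plet1 (3.81 ± 0.33), Sbpl (3.76 ± 0.41), the monoamine transporter Slc18a2 (3.60 ± 0.24), the phosphatase Dusp2 (3.36 ± 0.36) and Siglecf (3.23 ± 0.56). The largest decreases were in Defa25 (-3.06 ± 0.34), Mptx1 (-3.01 ± 0.32), Atf7 (-2.80 ± 0.38, with its other probe at -0.02), Defa17 (-2.78 ± 0.33), the Paneth angiogenin Ang4 (-2.73 ± 0.42) and Defa31 (-2.65 ± 0.33). Of 25 G2/M genes 24 were lower and 1 not called (camera adjusted p 8.74e-17). Among 25 S phase genes 24 were lower and 1 higher (2.55e-16), all 14 Paneth genes were lower (2.71e-09). Of 18 CBC genes 16 were lower and 2 higher (3.99e-09). Enteroendocrine genes were higher in 30 of 32 members and lower in 2 (8.65e-06), tuft genes were higher in 15 of 18 with 3 not called (0.000345). Of 18 cholesterol biosynthesis genes 13 were higher and 5 not called (0.00129), with the synthase Hmgcs1 at 1.58 ± 0.16. Enterocyte genes were higher in 15 of 26 members, lower in 1 and not called in 10 (0.000737). Lymphocyte markers were higher in 12 of 19 with 7 not called (0.00914), as were immediate-early and dissociation genes (12 of 19, 7 not called, 0.0151, with the call lost without non-irradiated mouse 7, 0.0654, and with the stricter filter). When adjusted over the list alone, 1 cholesterol gene was lower, 18 enterocyte genes and 13 lymphocyte markers were higher and the other counts were the same. Sox9 (1.07 ± 0.18), Bmi1 (0.62 ± 0.12), Hopx (1.15 ± 0.17), Chga (2.45 ± 0.50), Dclk1 (1.09 ± 0.42) and Cdkn1a (1.94 ± 0.22) were higher. Lgr5 (-2.25 ± 0.29), Olfm4 (-1.78 ± 0.28), Ascl2 (-1.66 ± 0.24), Lrig1 (-1.04 ± 0.16), Lyz1 (-1.80 ± 0.32) and Mki67 (-1.45 ± 0.22) were lower, and Muc2 (0.07 ± 0.22) and Alpi (0.48 ± 0.26) were not called. The call of Dclk1 was lost without non-irradiated mouse 1, 2, 4 or 7 (adjusted p 0.124, 0.0575, 0.059 and 0.0778) or with slide as a random block (0.109), and Alpi was called with mouse as a fixed block (0.0163). No list call held with an estimated correlation, where the adjusted p = 0.124 for G2/M, S phase and CBC, 0.165 for Paneth, 0.489 for enteroendocrine, 0.467 for tuft, 0.433 for cholesterol biosynthesis, 0.545 for enterocyte and immediate-early and 0.581 for the lymphocyte list.

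**Figure D2:**
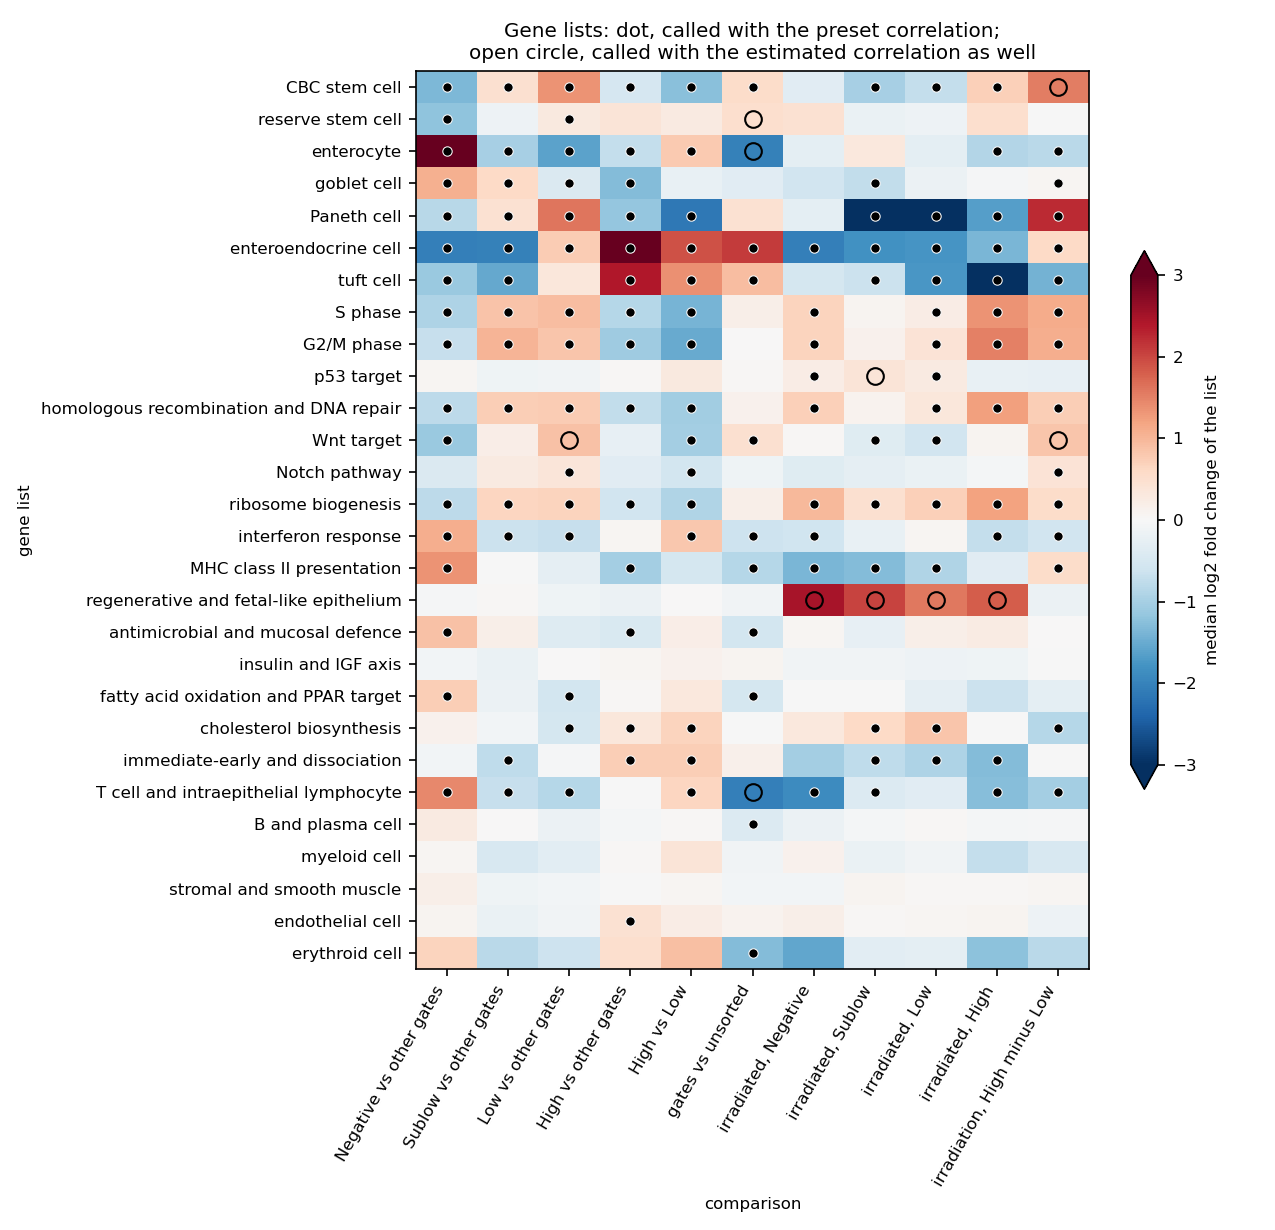
Median log2 fold change (colour) of each of the 28 gene lists (y axis) in each comparison (x axis); dots mark lists called by camera with the preset correlation and open circles those called with an estimated correlation as well. The regenerative list is called both ways in all 4 gates of irradiated mice, with medians of 2.47, 2.03, 1.58 and 1.81.

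The mean of the 4 gates was compared with unsorted cells, and 10902 of 27490 genes were called, 5738 higher and 5164 lower. Each gate had equal weight whatever its share of the epithelium, so these values do not show what the sort removed or enriched: Alpi, for example, had a mean log2 ratio to the pool of 0.35 in Negative, -0.04 in unsorted cells and -1.97, -2.95 and -2.47 in Sublow, Low and High. All 19 lymphocyte markers were lower (median -2.04, camera adjusted p 3.69e-25) and the call held with an estimated correlation (adjusted p = 0.0416). The natural killer receptor Klrd1 (-3.71 ± 0.29), the chemokine receptor Cxcr6 (-3.48 ± 0.24), Gzma (-3.47 ± 0.25) and the phosphatase Ptpn22 (-3.49 ± 0.23) were among the largest decreases, with Slc2a2 (-3.66 ± 0.30) and Cyp3a25 (-3.58 ± 0.28). All 26 enterocyte genes were lower as well (median -2.02, 6.99e-24; adjusted p = 0.0438 with an estimated correlation). Of 32 enteroendocrine genes 30 were higher and 2 not called (2.94e-16; adjusted p = 0.144 with an estimated correlation). Nts (3.16 ± 0.52), Chgb (3.16 ± 0.48), Cpe (3.02 ± 0.42), Scg2 (2.94 ± 0.44), Syt13 (2.72 ± 0.35) and Ambp (2.69 ± 0.42) had the largest increases. Of 6 reserve stem cell genes 4 were higher and 2 not called (0.00446; adjusted p = 0.0416 with an estimated correlation). Adjusted over the list alone, 31 enteroendocrine genes were higher and the other counts were the same. Sox9 (1.47 ± 0.14), Lgr5 (0.97 ± 0.23), Olfm4 (0.68 ± 0.22), Ascl2 (0.62 ± 0.19), Bmi1 (0.49 ± 0.09), Hopx (0.88 ± 0.16), Dclk1 (1.24 ± 0.33), Chga (2.40 ± 0.40) and Lyz1 (0.65 ± 0.25) were higher and Alpi (-1.73 ± 0.21) was lower. Lrig1 (0.26 ± 0.12), Muc2 (-0.38 ± 0.17), Mki67 (0.15 ± 0.17) and Cdkn1a (-0.07 ± 0.17) were not called. The call of Lyz1 was lost without non-irradiated mouse 2, 4, 5, 6 or 7 (adjusted p 0.054, 0.0811, 0.0762, 0.121 and 0.0869), and slide as a random block ended the calls of Lyz1, Olfm4 and Ascl2 (0.155, 0.0633 and 0.0502).

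Irradiation changed 12607 of 27491 genes in Negative (5210 up, 7397 down), 5114 of 27487 in Sublow (2430 up, 2684 down), 6539 of 27491 in Low (3096 up, 3443 down) and 10191 of 27489 in High (3642 up, 6549 down). In High 35.7% of the called genes rose, against 46.2% with the processed ratios of Feature Extraction, and in Low 47.3% against 51.3%. In all 4 gates 964 genes rose and 1151 fell; 1796 rose in both Negative and Sublow and 2574 fell in both Low and High. Arrays of the gates were not independent, so no expected overlap is given. Genes of a regenerative, fetal-like epithelium rose in every gate. Of 20 such genes, 16 rose, 1 fell and 3 were not called in Negative, 15 rose, 1 fell and 4 were not called in Sublow, 14 rose, 1 fell and 5 were not called in Low, and 14 rose, 3 fell and 3 were not called in High. The list was called in each gate, with camera adjusted p of 6.49e-14, 8.51e-22, 3.26e-14 and 3.13e-11, and with an estimated correlation adjusted p = 0.000743, 1.69e-05, 0.000744 and 0.00519. With p-values adjusted over the list alone, 16 rose in Sublow and 15 in Low, and the other counts were the same. Anxa1, a phospholipid-binding annexin, rose by 7.02 ± 0.31, 5.74 ± 0.31, 5.61 ± 0.31 and 6.57 ± 0.31, and its other probe by 4.86, 3.47, 3.46 and 4.10. Msln, a mesothelin of injured epithelia, rose by 5.49 ± 0.35, 4.31 ± 0.35, 3.91 ± 0.35 and 4.34 ± 0.35. Clu, clusterin, rose by 3.61 ± 0.20, 2.32 ± 0.20, 1.55 ± 0.20 and 1.37 ± 0.20. The gastric annexin Anxa10, which is not in the list, rose by 7.60 ± 0.46, 6.86 ± 0.46, 5.83 ± 0.46 and 4.66 ± 0.46. Nts, neurotensin, fell in every gate (-5.29 ± 0.88, -5.08 ± 0.88, -5.84 ± 0.88 and -5.01 ± 0.88).

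**Figure D3:**
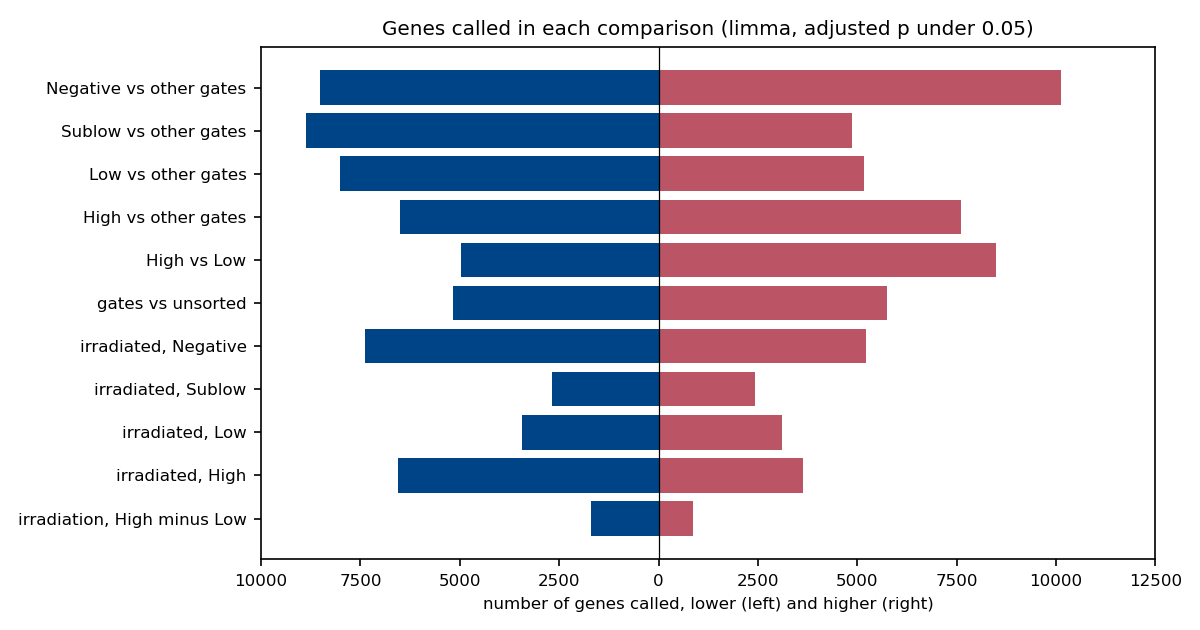
Number of genes called higher (right) and lower (left) in each comparison (y axis). Irradiation changed 12607 genes in Negative and 5114 in Sublow.

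In the Negative gate, irradiation raised Vsig1 (4.98 ± 0.35), a gastric junction protein, fibronectin Fn1 (4.39 ± 0.35) and the enkephalin gene Penk (4.31 ± 0.34), beside Anxa10, Anxa1 and Msln. Lymphocyte markers fell in 17 of 19 members with 2 not called (median -1.88, camera adjusted p 1.47e-07), with Gzma at -3.97 ± 0.42 and Cd8a at -2.62 ± 0.35. Among 32 enteroendocrine genes 28 fell, 1 rose and 3 were not called (5.25e-06), with the incretin gene Gip at -3.87 ± 0.74 and Scg2 at -3.67 ± 0.75. Of 22 ribosome biogenesis genes 19 rose and 3 were not called (4.76e-09), with nucleophosmin Npm1 at 1.42 ± 0.19. Of 25 S phase genes 15 rose, 2 fell and 8 were not called (0.000924), with Rrm2 at 2.29 ± 0.26. Of 20 repair genes 12 rose, 1 fell and 7 were not called (0.000484). Afp (-6.65 ± 1.17), Zfp488 (-4.90 ± 0.31), H2-Q4 (-4.43 ± 0.32) and Ambp (-3.90 ± 0.71) were the other largest decreases. The other Zfp488 probe gave 0.13, and Zfp488 and H2-Q4 belonged to 53 genes and probes with a non-irradiated Negative signal at least 4-fold above every other non-irradiated group. When adjusted over the list alone, 29 enteroendocrine genes and 18 lymphocyte markers fell, 14 repair genes rose and the other counts were the same. No list call other than that of the regenerative list held with an estimated correlation, where the adjusted p = 0.501 for the lymphocyte list, 0.443 for ribosome biogenesis and 0.664 for enteroendocrine, S phase and repair. Among the fixed markers, Olfm4 (-2.47 ± 0.37), Lgr5 (-1.12 ± 0.39), Chga (-3.53 ± 0.68) and Muc2 (-2.22 ± 0.29) fell. Bmi1 (1.02 ± 0.15), Cdkn1a (0.91 ± 0.30) and Alpi (0.83 ± 0.35) rose. Sox9 (0.28 ± 0.24), Ascl2 (0.38 ± 0.32), Hopx (-0.45 ± 0.26), Lrig1 (0.07 ± 0.21), Lyz1 (-0.46 ± 0.43) and Mki67 (0.43 ± 0.29) were not called, nor was Dclk1, which was not well above background on any irradiated Negative array. Lgr5 lost its call without irradiated mouse 1 or 3 or non-irradiated mouse 2 (adjusted p 0.0563, 0.0862 and 0.0527) and with slide as a fixed block (0.118). Cdkn1a lost it without irradiated mouse 2 (0.0516) and with the slide block (0.0902). Alpi lost it with the slide block (0.209, or 0.0565 as a random block) and without each of irradiated mice 2 and 3 (0.0824 and 0.132), each of non-irradiated mice 1 and 3 to 7 (0.0544 to 0.153), the Low array of non-irradiated mouse 3 (0.0533) or the High array of irradiated mouse 3 (0.0516). Hopx was called without non-irradiated mouse 1 (0.038).

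In the Sublow gate, Paneth and CBC stem cell genes fell. Of 14 Paneth genes 12 fell and 2 were not called (median -3.12, camera adjusted p 5.67e-17), and outside the list the cryptdins Defa25 (-4.41 ± 0.46), Defa42 (-4.39 ± 0.43), Defa29 (-4.29 ± 0.37), Defa31 (-4.25 ± 0.44) and Defa17 (-4.22 ± 0.44) were among the largest decreases. Among 18 CBC genes 12 fell and 6 were not called (1.14e-09), with Olfm4 at -3.60 ± 0.37 and Lgr5 at -2.75 ± 0.39, and the Wnt feedback gene Nkd1 fell by 2.44 ± 0.28. Of 32 enteroendocrine genes 20 fell and 12 were not called (2.91e-10). Of 16 goblet genes 8 fell and 8 were not called (0.000882), with Clca1 at -3.17 ± 0.54. Of 24 p53 target genes 12 rose, 3 fell and 9 were not called (0.00038), with Phlda3 at 2.23 ± 0.18 and Zmat3 at 1.35 ± 0.14, and this call held with an estimated correlation (adjusted p = 0.0167). Of 18 cholesterol biosynthesis genes 11 rose and 7 were not called (2.88e-06), with the cyclase Lss at 0.89 ± 0.17. Of 18 tuft genes 5 fell, 1 rose and 12 were not called (0.00628, with 0.0861 without non-irradiated mouse 3 and 0.108 with no array set term), of 19 immediate-early and dissociation genes 7 fell, 2 rose and 10 were not called (0.00259, and 0.058 without non-irradiated mouse 2), and of 19 lymphocyte markers 2 fell and 17 were not called (0.029, and 0.0548 on the moderated statistics). Vsig1 (4.83 ± 0.35), the alarmin Il33 (4.25 ± 0.28) and the surface protein Ly6d (4.15 ± 0.30) were among the largest increases. Adjusted over the list alone, 14 CBC, 13 Paneth, 22 enteroendocrine, 9 tuft and 9 immediate-early genes and 1 lymphocyte marker fell, 13 p53 targets and 13 cholesterol genes rose and the other counts were the same. The other calls did not hold with an estimated correlation, where the adjusted p = 0.0641 for Paneth, 0.0689 for CBC, 0.37 for enteroendocrine, 0.426 for goblet, 0.206 for cholesterol biosynthesis, 0.597 for tuft, 0.493 for immediate-early and 0.665 for the lymphocyte list. Lyz1 (-3.12 ± 0.43), Chga (-2.58 ± 0.68), Muc2 (-0.96 ± 0.29) and Lrig1 (-0.61 ± 0.21) fell. Alpi (1.20 ± 0.35) and Bmi1 (0.68 ± 0.15, with its other probe at 0.00) rose. Sox9 (-0.46 ± 0.24), Ascl2 (-0.86 ± 0.32), Hopx (-0.23 ± 0.23), Dclk1 (-1.33 ± 0.56), Mki67 (-0.26 ± 0.29) and Cdkn1a (0.66 ± 0.30) were not called, and Dclk1 was well above background on 1 of the 3 irradiated arrays. Calls were lost for Chga without irradiated mouse 1 (adjusted p 0.057), for Muc2 without irradiated mouse 1 or 2 or non-irradiated mouse 2 (0.0856, 0.0704 and 0.0619). They were also lost for Alpi without non-irradiated mouse 3 (0.0654) or with slide as a fixed block (0.108) and for Lrig1 without irradiated mouse 2 or 3 or non-irradiated mouse 1, 3 or 7 (0.197, 0.0705, 0.11, 0.0936 and 0.0812). Ascl2 was called without non-irradiated mouse 3, 4 or 6 (0.0175, 0.039 and 0.0452) or with the slide block (0.0386, or 0.0298 as a random block), Cdkn1a without non-irradiated mouse 3 (0.0446) and Dclk1 without non-irradiated mouse 5 (0.0147).

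In the Low gate, all 14 Paneth genes fell (median -3.77, camera adjusted p 2.46e-19), with the cryptdin Defa20 at -4.88 ± 0.55. The cryptdins Defa42 (-5.17 ± 0.43), Defa29 (-5.12 ± 0.37) and Defa31 (-4.77 ± 0.44), which are not in the list, and Zbtb46 (-5.03 ± 0.75) were also among the largest decreases. Of 18 tuft genes 16 fell and 2 were not called (3.64e-10), with Rgs13 at -4.63 ± 0.72. Among 32 enteroendocrine genes 24 fell and 8 were not called (3.06e-13), with Gip at -4.20 ± 0.74. Of 18 CBC genes 8 fell and 10 were not called (4.87e-06), with Olfm4 at -2.05 ± 0.37 and Lgr5 at -1.60 ± 0.39. Of 20 Wnt targets 10 fell, 1 rose and 9 were not called (7.42e-05), with Nkd1 at -2.62 ± 0.28. Of 19 immediate-early and dissociation genes 11 fell and 8 were not called (2.89e-06), with Egr1 at -2.34 ± 0.37. Of 18 cholesterol biosynthesis genes 14 rose and 4 were not called (1.34e-09), with the cyclase Lss at 1.28 ± 0.17. Of 22 ribosome biogenesis genes 18 rose and 4 were not called (5.77e-09). The stem cell antigen family member Ly6c1 (4.73 ± 0.28, with its other probe at 0.67), Anxa3 (4.61 ± 0.36), Il33 (4.40 ± 0.28) and the aldo-keto reductase Akr1b8 (4.12 ± 0.33) were among the largest increases. With p-values adjusted over the list alone, 12 CBC, 12 Wnt target, 29 enteroendocrine and 12 immediate-early genes fell, 1 immediate-early and 19 ribosome biogenesis genes rose and the other counts were the same. No call of these lists held with an estimated correlation, where the adjusted p = 0.0537 for Paneth, 0.176 for tuft and Wnt targets, 0.186 for enteroendocrine, ribosome biogenesis and immediate-early, 0.183 for CBC and 0.0895 for cholesterol biosynthesis. Lyz1 (-3.81 ± 0.43), Dclk1 (-3.07 ± 0.56), Chga (-2.62 ± 0.68) and Sox9 (-0.66 ± 0.24) fell, Bmi1 rose (0.62 ± 0.15, with its other probe at -0.14). Dclk1 was well above background on 2 of the 3 irradiated Low arrays. Ascl2 (-0.84 ± 0.32), Hopx (-0.64 ± 0.26), Lrig1 (-0.06 ± 0.21), Muc2 (-0.27 ± 0.29), Alpi (0.89 ± 0.35), Mki67 (-0.05 ± 0.29) and Cdkn1a (0.12 ± 0.30) were not called. Chga lost its call without irradiated mouse 2 (adjusted p 0.0662). Sox9 lost it without irradiated mouse 1, 2 or 3 (0.0509, 0.166 and 0.0519), without non-irradiated mouse 2, 3, 4 or 7 (0.0741, 0.0678, 0.0564 and 0.0545), without the Low array of non-irradiated mouse 3 (0.0791) and with the processed ratios of Feature Extraction (0.087, with a range over all alternatives of 0.0177 to 0.169). Ascl2 was called without non-irradiated mouse 3 or 5 (0.00456 and 0.0315), without the Low array of mouse 3 (0.0476) or with slide as a fixed or random block (0.0446 and 0.0324). Hopx was called without non-irradiated mouse 1 (0.0277) or with these slide blocks (0.0172 and 0.0304), and Alpi without irradiated mouse 1 or 3 or non-irradiated mouse 2 or 5 (0.0404, 0.0167, 0.0387 and 0.0353) or with slide as a random block (0.0486).

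In the High gate, tuft cell genes fell and genes of dividing cells rose. Of 18 tuft genes 15 fell and 3 were not called (median -3.66, camera adjusted p 1.01e-13), with Rgs13 at -7.32 ± 0.72 and Ptgs1 at -4.85 ± 0.58. The tuft-enriched Spib (-5.88 ± 0.42), Sh2d7 (-5.81 ± 0.52, with its other probe at -1.75) and Alox5 (-5.49 ± 0.55) and Afp (-7.58 ± 1.17) were the other largest decreases. Of 25 G2/M genes 23 rose and 2 were not called (3.33e-15). Among 25 S phase genes 22 rose, 1 fell and 2 were not called (3.33e-15). Of 20 repair genes 17 rose and 3 were not called (2.35e-12). Of 22 ribosome biogenesis genes 21 rose and 1 was not called (2.49e-17). The S phase gene Rrm2 (2.77 ± 0.26), the repair gene Exo1 (2.07 ± 0.27) and the G2/M gene Bub1 (1.95 ± 0.29) were among those that rose. Among 18 CBC genes 9 rose, 2 fell and 7 were not called (median 0.72, 0.0047), with Lgr5 at 1.15 ± 0.39 and Smoc2 at 0.97 ± 0.23. Pla2g5 (4.12 ± 0.37), a phospholipase, Akr1b8 (4.08 ± 0.33) and Mboat1 (3.96 ± 0.26), an acyltransferase, were among the largest increases. Of 32 enteroendocrine genes 19 fell, 1 rose and 12 were not called (0.000235). Of 14 Paneth genes 12 fell and 2 were not called (0.00316). Lymphocyte markers fell in 16 of 19 members, rose in 1 and were not called in 2 (4.03e-05), with Gzma at -3.43 ± 0.42. Of 19 immediate-early and dissociation genes 15 fell and 4 were not called (0.000206). Of 26 enterocyte genes 14 fell and 12 were not called (median -0.88, 0.00158). When adjusted over the list alone, 17 tuft and 22 enteroendocrine genes fell, 23 S phase, 10 CBC and 1 enterocyte genes rose and the other counts were the same. No call of these lists held with an estimated correlation, where the adjusted p = 0.112 for tuft, S phase, repair and ribosome biogenesis, 0.171 for G2/M, 0.501 for CBC and the lymphocyte list, 0.528 for enteroendocrine, Paneth and enterocyte and 0.446 for immediate-early. The enterocyte call was also lost without irradiated mouse 1 (0.0885), and the Paneth call without irradiated mouse 3 (0.0665) or its High array (0.0617) and with slide as a fixed block (0.174). Lrig1 (1.08 ± 0.21), Ascl2 (0.91 ± 0.32) and Mki67 (1.12 ± 0.29) rose. Dclk1 (-4.33 ± 0.56), Chga (-1.94 ± 0.68), Lyz1 (-1.80 ± 0.43), Hopx (-1.18 ± 0.23), Cdkn1a (-1.18 ± 0.30) and Sox9 (-0.60 ± 0.24) fell. Olfm4 (0.09 ± 0.37), Bmi1 (0.05 ± 0.15), Muc2 (-0.33 ± 0.29) and Alpi (0.21 ± 0.35) were not called. Leaving out irradiated mouse 1 or 2 or non-irradiated mouse 3 ended the calls of Lgr5 (adjusted p 0.0764, 0.0689 and 0.0806), Ascl2 (0.106, 0.076 and 0.0849) and Chga (0.0592, 0.115 and 0.0605). Sox9 lost its call without irradiated mouse 1 or 2 (0.235 and 0.245), without non-irradiated mouse 1, 2, 3 or 7 (0.0596, 0.068, 0.0988 and 0.0546) and with the processed ratios of Feature Extraction (0.165, with a range over all alternatives of 0.00354 to 0.245), and Lyz1 with the slide block (0.0803).

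**Figure D4:**
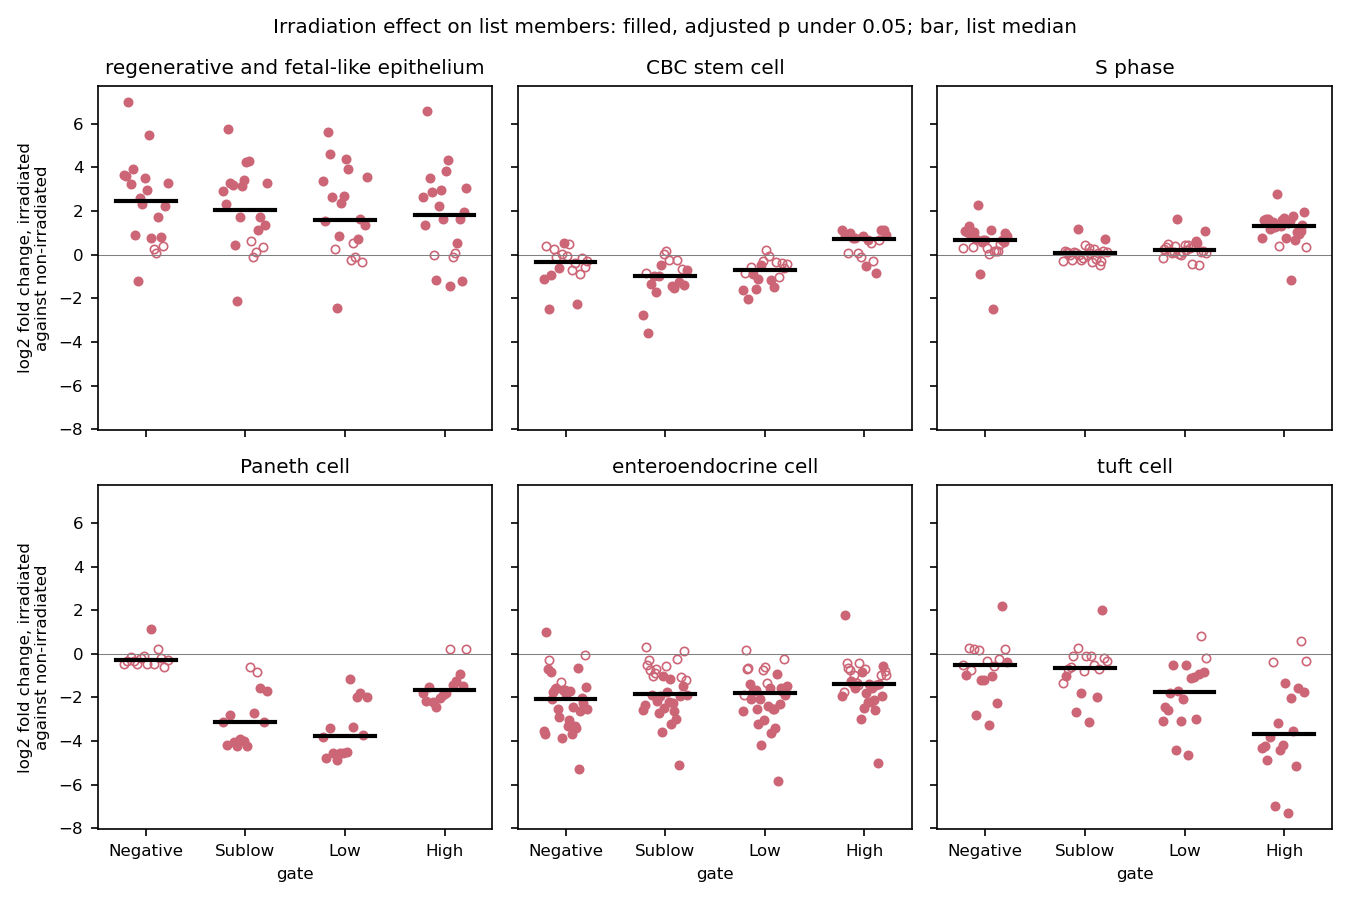
Log2 fold change of irradiated against non-irradiated cells (y axis) for each member of 6 gene lists by gate (x axis), each point 1 gene, filled where called, with a bar at the list median. The Paneth median lies at -3.77 in Low and -1.65 in High, the tuft median at -1.75 in Low and -3.66 in High, and the CBC median at -0.73 in Low and 0.72 in High.

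Whether irradiation acted differently in different gates was tested directly. The effect differed among the 4 gates for 10672 of 27485 genes, and between High and Low for 2556 of 27489 genes, 867 more positive in High (33.9%) and 1689 more negative, against 48.5% more positive with the processed ratios of Feature Extraction. The irradiation effect on CBC and Wnt target genes was more positive in High than in Low. The lists share Lgr5, Ascl2, Axin2, Rnf43, Znrf3, Ephb3 and Tnfrsf19, so their results are not independent. Of 18 CBC genes 14 were more positive in High, 1 more negative and 3 not called (median 1.54, camera adjusted p 4.31e-16; adjusted p = 0.0158 with an estimated correlation). Of 20 Wnt targets 10 were more positive and 10 not called (2.12e-11; adjusted p = 0.0158 with an estimated correlation). Lgr5 differed by 2.75 ± 0.53, Olfm4 by 2.13 ± 0.51, Ascl2 by 1.75 ± 0.43, Lrig1 by 1.14 ± 0.28 and the glutamine transporter Slc38a5, the largest positive difference outside the cryptdins, by 2.94 ± 0.30. Of 14 Paneth genes 11 were more positive and 3 not called (3.66e-13), with Lyz1 at 2.01 ± 0.59, and outside the list the cryptdins Defa17 (3.04 ± 0.60), Defa31 (2.88 ± 0.60), Defa25 (2.86 ± 0.62) and Defa40 (2.83 ± 0.59) were more positive. Lyz1 fell in both gates, its mean log2 ratio to the pool going from 1.81 to -2.34 in Low and from 0.00 to -2.14 in High. Of 25 S phase genes 15 were more positive and 10 not called (3.22e-16), with the licensing factors Cdt1 at 1.44 ± 0.29 and Cdc6 at 1.37 ± 0.28. Of 18 tuft genes 6 were more negative in High and 12 not called (1.9e-06). Of 19 lymphocyte markers 5 were more negative and 14 not called (median -1.03, 2.4e-05), and of 26 enterocyte genes 4 were more negative and 22 not called (0.000402). Of 18 cholesterol biosynthesis genes 10 were more negative and 8 not called (1.54e-08), with Hmgcs1 at -1.69 ± 0.29. The GTPase Rac2 (-3.58 ± 0.55), Plet1 (-3.28 ± 0.61), Siglecf (-3.22 ± 1.02), the renin gene Ren2 (-3.20 ± 0.63), the lysophospholipase Enpp2 (-3.04 ± 0.61) and Lrmp (-2.93 ± 0.72) had the most negative differences, and Cdkn1a differed by -1.30 ± 0.41. Adjusted over the list alone, 16 CBC, 13 Wnt target, 13 Paneth and 20 S phase genes were more positive, 1 lymphocyte marker more positive, 1 S phase, 13 tuft, 12 cholesterol and 7 enterocyte genes and 12 lymphocyte markers more negative, and the other counts were the same. With an estimated correlation the adjusted p = 0.0725 for Paneth, S phase and cholesterol biosynthesis, 0.272 for tuft, 0.356 for the lymphocyte list and 0.484 for enterocyte. Sox9 (0.06 ± 0.32), Bmi1 (-0.57 ± 0.21), Hopx (-0.54 ± 0.33), Dclk1 (-1.26 ± 0.77), Chga (0.68 ± 0.92), Muc2 (-0.06 ± 0.40), Alpi (-0.68 ± 0.48) and Mki67 (1.17 ± 0.40) did not differ by the test. Differences of list effects between other pairs of gates were not tested.

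The number of genes with a different effect in High and Low depended on single mice. It was 570 without irradiated mouse 1, 1100 without irradiated mouse 2, 1621 without non-irradiated mouse 7 and 3960 without the Low array of non-irradiated mouse 3. With slide as a fixed block in mice 1 to 3 it was 329, of which 61.4% were more positive. The number that differed among the 4 gates was 6343 without irradiated mouse 2 and 4616 with the slide block. The calls of Lgr5, Slc38a5, Rac2, Plet1, Defa25, Hmgcs1, Cdc6 and Cdt1 were kept in each of these settings. Without irradiated mouse 1 or 2, Ascl2 (adjusted p 0.0568 and 0.0895), Olfm4 (0.0524 and 0.0721) and Lyz1 (0.0977 and 0.121) lost theirs, as did Lrig1 without irradiated mouse 2 (0.146) and Lrmp without irradiated mouse 1 (0.145). With the slide block the adjusted p was 0.0585 for Olfm4, 0.101 for Lyz1, 0.061 for Defa17, 0.0691 for Defa31, 0.0555 for Defa40, 0.0822 for Enpp2, 0.0812 for Lrmp, 0.0801 for Ren2, 0.108 for Siglecf and 0.119 for Cdkn1a. Siglecf lost its call without irradiated mouse 1, 2 or 3 (0.143, 0.105 and 0.136), without non-irradiated mouse 1, 2, 4 or 7 (0.0669, 0.0666, 0.0624 and 0.0771) and without the High array of irradiated mouse 3 (0.0723). Cdkn1a lost it without irradiated mouse 1 or 2 (0.234 and 0.277) or non-irradiated mouse 1, 2, 5 or 7 (0.065, 0.0644, 0.055 and 0.0609). Bmi1 was called without non-irradiated mouse 5 (0.0284), without the Low array of mouse 3 (0.0428) or with mouse as a random block (0.0475). Mki67 was called without non-irradiated mouse 1, 3 or 6 (0.0348, 0.0494 and 0.0323), without the Low array of mouse 3 (0.0334) or with mouse (0.0374) or slide (0.0404) as a random block.

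Whether irradiated High cells lay along the difference between Low and High was asked with arrays that the measures did not share. Across 27480 genes, the irradiation effect in High of mice 1 to 3 and the Low minus High difference of non-irradiated mice 4 to 7 had a Pearson r of 0.683, and 71.5% of genes had the same sign. Genes are not independent replicates, so no p is given. The Low arrays of mice 4 to 7 lay on 1 slide and the High arrays on another, so a slide difference could not be separated from that gate difference. The processed ratios of Feature Extraction gave 0.58, and leaving out 1 mouse at a time gave 0.625 to 0.715. With the High arrays of mice 1 to 3 shared by both measures r was 0.71, where simulated groups with no change gave a median of 0.5 from the shared arrays alone.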

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

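For the regroupings of arrays and the tests of shared arrays, shared probe sequence, genomic DNA and High cells among Low cells, the prediction was written before the result was seen. The tests of scan session, slide and lymphocytes, of Negative cells or irradiated Low cells in irradiated High, and of an exchange of arrays were chosen after seeing the pattern.

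The regroupings used the 25798 genes with a value on every array and only the arrays of each comparison, so their counts differ from those above. A gate, or the unsorted cells, was set against the other non-irradiated arrays pooled as 1 group. In these fits the real grouping called 15089 genes for Negative, 4577 for Sublow, 4246 for Low, 9146 for High and 3043 for gates against unsorted cells. The other groupings drew 1 array per mouse at random. Of 100 groupings, the real one included, 1, 2, 4, 1 and 3 called as many, and the highest other counts were 6957, 6500, 8799, 4237 and 5770. The drawn groups mixed arrays of different gates, so a draw rich in 1 gate could call differences between gates. These draws therefore do not show the counts to be had without gate differences. The make-up of the groupings that called more than the real one was not tested. With High and Low exchanged within mice, 1 of 64 groupings reached the real 13324 (highest other 9082). For irradiation, with 3 of 10 arrays of a gate drawn, 1 of 100 groupings reached the real count in each case: 6539 in Negative (highest other 802), 4594 in Sublow (2), 3690 in Low (164), 7816 in High (243), 9623 for any difference among gates (5165) and 1501 for High minus Low (681). These draws kept neither the slides shared by irradiated and non-irradiated arrays nor the array set, which stayed a term of the fit.

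Single arrays stood apart from the other 6 of their group for 5 of 70 combinations of marker and group, where chance gives about 1 in 20. They were Sox9 in unsorted cells of mouse 3 (-0.428), Olfm4 in High of mouse 3 (-1.72), Hopx in Low of mouse 3 (1.91), Chga in unsorted cells of mouse 5 (0.526) and Cdkn1a in High of mouse 3 (2.06), all non-irradiated.

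Irradiation effects that differed between gates by the interaction test were counted for 10672 genes among the 4 gates and 2556 genes between High and Low. More positive in High were Lgr5 (2.75), Olfm4 (2.13), Ascl2 (1.75), Lrig1 (1.14), Lyz1 (2.01), Defa17 (3.04), Defa25 (2.86), Defa31 (2.88), Defa40 (2.83), Slc38a5 (2.94), Cdc6 (1.37) and Cdt1 (1.44). More negative in High were Cdkn1a (-1.30), Rac2 (-3.58), Plet1 (-3.28), Siglecf (-3.22), Ren2 (-3.20), Enpp2 (-3.04), Lrmp (-2.93) and Hmgcs1 (-1.69).

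In the non-irradiated Negative gate, 53 genes and probes, most without a gene symbol, had a signal at least 4-fold above every other non-irradiated group, and all 53 fell with irradiation. They were chosen for a high signal on the same arrays that the fall was measured from, so the choice favoured a fall. Of 63 genes and probes chosen in the first array set alone, 46 were among the 53. The median log2 excess of the 63 over unsorted cells was 2.97 in that set and 2.73 (jackknife SE 0.229) in the second. This argues against a scan session of the first set. For the 53, the median excess was -0.814 in irradiated Negative arrays, which shared slides with the non-irradiated Negative arrays of mice 1 to 3. This argues against those slides as the source. The Negative arrays of mice 4 to 7 shared 1 slide with no other group, so an effect of that slide could not be tested. The lymphocyte list lay below unsorted cells (-1.07, SE 0.236), which argues against lymphocytes as the source of the excess. That level does not show that the gate lacked lymphocytes, since 17 of 19 markers were higher there than in the other gates. Of the 53 probes, 7 shared at least 20 bases with another (highest of 1000 random sets 3), too few to account for all and too many to dismiss, so a shared sequence may contribute. Genomic DNA could not be excluded: receptor probes of silent genes lay 0.0772 (SE 0.0163) above unsorted cells, under the bound written for the test, but only 38.3% of their spots were well above background, so little DNA signal could have been seen.

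The irradiation effect in High ran along the Low minus High difference, as a change of High cells or as another mix of cells in the gate could produce. Shared arrays could not account for the r of 0.683, since no array entered both of its measures. The prediction set it against simulations with sharing, which gave at most 0.517, but that comparison adds nothing where no array is shared. The r with shared arrays was 0.71. A mixture lies between its sources, and cells of the Negative gate were argued against for the S phase and CBC lists, which in irradiated High lay above both non-irradiated High and irradiated Negative, by medians of 0.688 (jackknife SE 0.249) and 0.712 (SE 0.209); they remained possible for the G2/M list (0.324, SE 0.241), for 995 genes higher in Low than in High (0.128, SE 0.171) and for 2460 genes lower in Low (-0.411, SE 0.223, negative values lying between the sources). Cells of the irradiated Low gate could account for the 995 genes (-0.359, SE 0.173) and the 2460 genes (-0.561, SE 0.23), while the S phase (-0.287, SE 0.203), G2/M (-0.376, SE 0.222) and CBC (0.111, SE 0.165) lists left this open, as did medians of arrays for the enterocyte list (-0.49, SE 0.622) against non-irradiated High and for the CBC list (0.28, SE 0.171) against irradiated Low. Distances beyond both sources were taken from the higher or lower of noisy means, which makes them more negative. The SE does not include this, so a negative value alone does not show a mixture. The gate was set on non-irradiated mice, and reporter levels per cell were not analysed here.

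The Low array of non-irradiated mouse 3 lay 0.619 of the way from Low toward High, compared with the other arrays of its set. An exchange with the High array of the same mouse was argued against, because that array lay 0.261 toward High rather than toward Low. High cells among the sorted Low cells could account for the shift: the enteroendocrine list was 2.42 (SE 0.402) and the tuft list 1.33 (SE 0.803) above, and the S phase list -0.659 (SE 0.0624) from, the other Low arrays of that set. The tuft value lay within 2 SE, so this was not settled, and no biological explanation was tested.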

How the results depend on the processing

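The scan session covariate and the 2 fits without a single array were chosen after seeing the data; all other alternatives were written before the data were examined. No named gene or list reversed its direction with a call in any alternative. With mice 1 to 3 alone, fewer arrays called fewer genes: 6829 for Sublow, 5215 for Low, 7267 for High against Low, 3143 for irradiation in Sublow, 3814 for a difference among the 4 gates, 211 for High minus Low and 5226 for gates against unsorted cells. In that fit 45 calls of named genes or lists were lost and 10 gained, and for High minus Low those of Plet1, Hmgcs1, Cdc6 and Cdt1 were among the lost. With slide as a fixed block in mice 1 to 3, also fewer arrays, 4616 genes differed among the 4 gates and 329 between High and Low. Leaving out 1 mouse at a time gave 6343 (without irradiated replicate 2) to 11534 (without non-irradiated replicate 3) genes for any difference among gates, and 570 (without irradiated replicate 1) to 3623 (without non-irradiated replicate 3) for High minus Low, with 1100 without irradiated replicate 2 and 1621 without non-irradiated replicate 7; the cause was not tested. Without the non-irradiated Low array of mouse 3 the latter count was 3960, and without the irradiated High array of mouse 3 it was 3569. With the scan session covariate 9260 genes differed among the 4 gates and 2794 between High and Low. The correlation of the irradiation effect in High with the Low minus High difference was 0.58 with the processed ratios of Feature Extraction and with the authors' series values, which hold the same ratios, and 0.625 (without non-irradiated replicate 3) to 0.715 (without non-irradiated replicate 1) with 1 mouse left out, with 0.632 without irradiated replicate 1; the cause was not tested. The stricter filter moved the median of all genes to 0.105 for High against Low, -0.103 for irradiation in High and -0.101 for High minus Low. Aquantile scaling leaves 2-colour ratios unchanged and tested nothing. The blocked fits changed no call stated in the report other than those given there. Arrays with 56.0% of probes above background limit what can be said of weakly expressed genes.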

Other observations

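The tests of this part are those planned for all lists, and none was chosen after seeing the result. Metabolic and signalling lists not yet described also divided the gates. Of 20 fatty acid oxidation and PPAR target genes, 17 were higher in Negative, 2 lower and 1 not called (median 0.74, camera adjusted p 0.000784; adjusted p = 0.397 with an estimated correlation). In Low, 14 of them were lower, 3 higher and 3 not called (0.000811; adjusted p = 0.292 with an estimated correlation), and adjusted over the list alone 15 were lower. Of 14 Notch pathway genes, 10 were lower in High than in Low, 3 higher and 1 not called (0.00461; adjusted p = 0.124 with an estimated correlation). The irradiation effect on 3 Notch genes was more positive in High than in Low and 11 were not called (0.000498; adjusted p = 0.0687 with an estimated correlation). Of 15 antimicrobial and mucosal defence genes, 11 were lower in High and 4 not called (0.00212; adjusted p = 0.3 with an estimated correlation). Of 8 MHC class II presentation genes, 4 fell with irradiation in Sublow and 4 were not called (median -1.31, 0.000882; adjusted p = 0.291 with an estimated correlation), and adjusted over the list alone 7 fell. Of 16 genes of the insulin and IGF axis, 3 fell with irradiation in Low and 13 were not called, and the list was not called (0.115; adjusted p = 0.183 with an estimated correlation).

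Markers of cells outside the epithelium were lower in the gates than in unsorted cells for some types. Of 10 B and plasma cell genes 5 were lower and 5 not called (0.00254; adjusted p = 0.134 with an estimated correlation), and of 6 erythroid genes 5 were lower and 1 not called (0.00071; adjusted p = 0.131 with an estimated correlation). Of 12 stromal and smooth muscle genes 4 were lower, 1 higher and 7 not called, and the list was not called (0.145; adjusted p = 0.501 with an estimated correlation). Of 10 endothelial genes 4 were higher, 1 lower and 5 not called (0.0763; adjusted p = 0.252 with an estimated correlation), and of 15 myeloid genes 7 were lower, 3 higher and 5 not called (0.0776; adjusted p = 0.314 with an estimated correlation), and neither list was called. In High against the other gates, 7 endothelial genes were higher and 3 not called (0.0114; adjusted p = 0.3 with an estimated correlation). With irradiation in High, 7 myeloid genes fell, 2 rose and 6 were not called, and the list was not called (0.069; adjusted p = 0.446 with an estimated correlation), nor was it in Low, where 3 fell and 2 rose (0.557; adjusted p = 0.868 with an estimated correlation). On the array of the pool against itself 0% of probes differed by over 2-fold, against 0.107% to 2% on the arrays of unsorted cells.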
